A study of Macaca mulatta with 49 samples.

How the data were processed

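Total RNA of sorted CD8 and CD4 TCM of 12 rhesus macaques, before and after anti-IL-15 or an IgG1 control antibody, was amplified by the authors and hybridised to Illumina human BeadChips with 47230 probes. The deposited non-normalized table holds the mean bead intensity of each probe on each array, in whole numbers. Beside each intensity the table holds a detection p-value per the file headers, which compares the probe with the background of its array. The deposited value table holds log2 values, and 99.9% of them lay within 0.001 of the log2 quantile-normalized intensity recomputed here, so the authors' table carries no background correction. Per the labels the authors used limma, with no version or role given. Readings of 0 in the intensities, 49 in number, were treated as missing. Sample group, time point, antibody, animal and sorted cell count came from the labels; the misspelt time point on the control samples was read as post-treatment. The labels give neither the time since treatment nor the dose.

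The probes were designed on human sequence, so a probe without signal in macaque RNA does not show that the gene was silent, and sequence differences can lower a signal. Of the probes, 30113 carried 1 gene symbol, 8 several and 17109 none in the annotation used; the last 2 kinds were left out of the gene tests. No coordinates are given, because the array table names no genome build.

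Intensities were background corrected, quantile normalized over 49 arrays and log2 transformed with neqc of limma 3.58.1 in R 4.3.3 (offset 16, background from the detection p-values), and figures were drawn in Python 3.11.15. The 2 arrays of the repeated sample were averaged. A probe was kept where its detection p-value was below 0.05 in at least 6 of the 24 samples of a cell type, and of several probes of a gene the one with the highest mean was tested, which left 8626 genes in CD8, 8923 in CD4 and 9355 in fits of both. Median intensity ran from 88 to 103 on CD8 arrays and from 96 to 108 on CD4 arrays, and 11448 to 13720 and 11993 to 14870 probes were detected; the number of arrays limits the precision.

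Each cell type was fitted apart with limma (lmFit and eBayes), with the animal as a fixed block and 1 post-treatment term per antibody. The block is the animal named in the labels, so the samples are paired. Within a group, pre-treatment and post-treatment samples of an animal correlated, relative to the group mean, with a median r of 0.403 in CD8 anti-IL-15, 0.386 in CD8 IgG1, 0.224 in CD4 anti-IL-15 and 0.401 in CD4 IgG1. The pair was the best match for 5, 6, 4 and 6 of the 6 animals. Fits of all 48 samples used animal by cell type as the block (24 blocks), and CD8 against CD4 before treatment was fitted with the animal as the block. The antibody groups before treatment were compared without a block. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A fold against a cell type in which no array detected the gene is given as a lower bound.

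The naming rule was as follows. For each comparison after treatment, up to 12 genes higher and 12 lower with the largest change were named among those past the threshold and of the same direction in all 6 animals; where fewer than 5 passed, the 5 with the lowest p were named. For CD8 against CD4, 10 in each direction were named. Detected genes of the IL-15 list and up to 4 members of each list with the lowest p could be named as well. The rule, the comparisons, the alternatives and 26 gene lists (17 of pathways and 9 of cell type markers) were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison, and their members were counted over all genes and adjusted over the list alone. The fry results are not given below. Sorted cell counts were compared by exact sign-flip tests within animals and exact permutation of the antibody labels.

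The fits were tested on simulated data with 200 changed genes at the observed spread. Noise was drawn independently for each gene, so variation shared between genes is absent. With fewer changed genes the adjusted threshold is stricter, so recovery would be lower than given here. For CD8 TCM after anti-IL-15 (8623 genes) a change of 0.5 was recovered for 29.9% of 67 genes, one of 1 for 95.5% of 67 and one of 2 for 100% of 66. For CD4 TCM after anti-IL-15 (8919 genes) these were 29.9% of 67, 100% of 67 and 100% of 66. For CD8 against CD4 (9350 genes) they were 82.1% of 67, 100% of 67 and 100% of 66.

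Alternatives were the deposited value table, normexp with offset 50, no background correction, no filter or a stricter filter on dim probes, every probe of a gene, a variance trend with robust moderation, array weights, the sorted cell count as a covariate, each animal left out in turn, a threshold of 0.1, no replicate block, the block as a random effect and both cell types in 1 fit. Animals 1 to 4 alone, animals 5 and 6 alone, and the removal of animals whose arrays stood apart were added after seeing the data. A block for the BeadChip was not run, because the chip of an array is not named.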

Results

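Gene expression was measured on human Illumina BeadChips in central memory T cells (TCM) sorted from the blood of 12 rhesus macaques. Of these animals, 6 received an antibody against interleukin 15 (IL-15), a cytokine that sustains memory T cells and natural killer (NK) cells, and 6 received an IgG1 control antibody. CD8 and CD4 TCM were sorted from each animal before and after treatment, which gives 8 groups of 6 samples. The 48 samples were run on 49 arrays, because 1 CD8 sample was hybridised on 2 arrays. Detected signal was found for 24.2% to 29.0% of the 47230 probes on the CD8 arrays and for 25.4% to 31.5% on the CD4 arrays. The number of sorted cells behind a sample ranged from 23000 to 116000 for CD8 and from 197000 to 958000 for CD4. The 2 arrays of the repeated sample correlated at r = 0.990 across probes, above the 0.937 to 0.982 between different animals of a CD8 group. Probes are not independent replicates. The first principal component held 26.6% of the variance and parted CD8 from CD4. The next held 8.36%, and samples of animals 5 and 6 of each antibody group lay toward one end of it, overlapping with a few samples of animals 1 to 4. The CD8 post-treatment array of anti-IL-15 animal 4 (median r with the other CD8 samples 0.956) and the CD4 arrays of anti-IL-15 animal 3 before (0.956) and after treatment (0.961) stood apart from their cell type. Values below are log2 intensities, and errors of changes are moderated standard errors (SE) of limma, which pool the spread over the animals of both antibodies; the number of arrays limits their precision.

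In CD8 TCM after anti-IL-15, 3 genes of cytotoxic granules were higher than before treatment, as were single genes of cytokine feedback and of the interferon response. IFI27, an interferon-inducible gene, rose by 1.67 ± 0.22 on the log2 scale (moderated SE, 12 animals in the fit), which is 3.18-fold (adjusted p = 0.00859). SOCS3, a feedback inhibitor of cytokine signalling through JAK and STAT proteins, rose by 1.29 ± 0.20 (adjusted p = 0.0227). The granule genes GNLY (granulysin), GZMK (granzyme K) and NKG7 rose by 1.21 ± 0.21, 1.16 ± 0.22 and 0.98 ± 0.19. The growth arrest and stress genes GADD45A and GADD45B rose by 1.20 ± 0.23 and 0.91 ± 0.14. SLC2A3, a glucose transporter, rose by 1.03 ± 0.17, the acid-sensing receptor GPR65 by 1.00 ± 0.18, and DUSP5, a phosphatase of ERK kinases, by 0.99 ± 0.19. GBP1P1, annotated as a pseudogene of an interferon-inducible GTPase, rose by 0.92 ± 0.17, and IFFO1 rose by 0.79 ± 0.15. PDE9A, a phosphodiesterase of cyclic GMP, fell by 0.96 ± 0.19, and AGER, a receptor for glycated proteins, fell by 0.85 ± 0.16. Each of these 14 genes moved the same way in 6 of 6 animals, with adjusted p values up to 0.0476 in limma. The remaining gene, TENT5C, rose by 1.13 ± 0.20 and was higher in 5 of 6 animals. It falls outside the naming rule and was named after its values were seen. In all, 15 of 8626 genes passed the threshold, 13 higher and 2 lower, and 811 had an unadjusted p under 0.05. The dimmer probes of SOCS3 and GPR65, not used for the test, gave 0.03 and -0.11, while that of GADD45A gave 1.81 and that of AGER gave -0.47. The count was 4 without IgG1 animal 1, 2 or 3, 3 without IgG1 animal 4. It was 2 without anti-IL-15 animal 1, 1 without anti-IL-15 animal 2, and 4 without anti-IL-15 animal 3, 4 or 5. It was 0 without the animal as replicate block and without a filter on dim probes. IFI27 passed in each of the 12 fits that left out 1 animal. SOCS3 passed in 9 of these fits, GADD45B in 8 and SLC2A3 in 7. The granule genes passed in few of them, GNLY in 3, GZMK in 2 and NKG7 in 1.

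**Figure D1:**
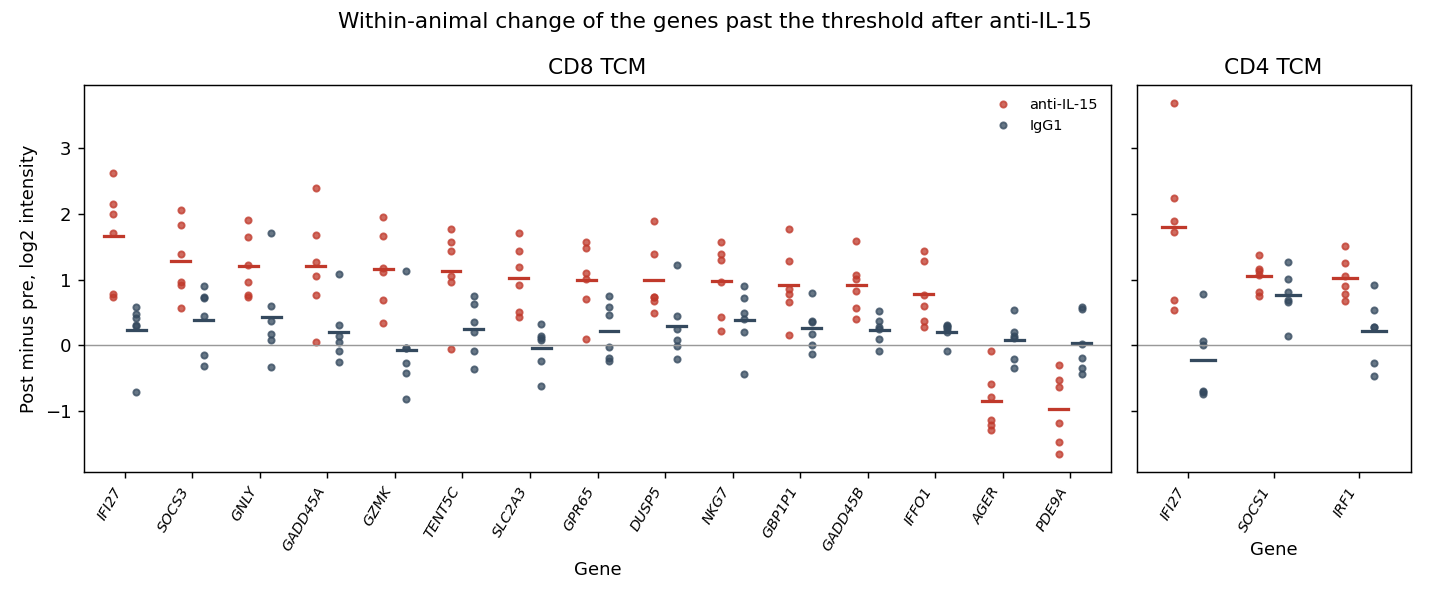
Post-treatment minus pre-treatment log2 intensity of each gene past the threshold after anti-IL-15, in CD8 TCM (15 genes) and CD4 TCM (3 genes). Each point is 1 of 6 animals per antibody and each bar is their mean; IFI27 in CD8 TCM averaged 1.67 after anti-IL-15 and 0.23 after IgG1.

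Gene lists in CD8 TCM after anti-IL-15 showed the same granule theme. Of 11 cytotoxic effector genes, 3 rose over all genes tested and 8 adjusted over the list alone, with a mean change of 0.68 (camera adjusted p = 6.84e-10, and adjusted p = 0.0263 with an estimated correlation). GZMH in this list had a change of 1.47 (adjusted p = 0.12) and GZMA one of 1.14 (adjusted p = 0.23). Of 8 NK cell markers, 1 rose over all genes (GNLY, also a cytotoxic list member) and 3 adjusted over the list alone (adjusted p = 0.000112, and adjusted p = 0.0263 with an estimated correlation). KLRD1, shared with cytotoxic T cells, had a change of 1.09. Of 13 regulators of effector differentiation, 0 passed in limma over all genes and 6 rose adjusted over the list alone (adjusted p = 0.000235, and adjusted p = 0.0263 with an estimated correlation). Their lowest p values were for BHLHE40 at 1.06, NFIL3 at 0.83 and PRDM1 at 0.75. Both kinds of camera test called these 3 lists.

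Other lists of CD8 TCM were called higher after anti-IL-15 with the preset correlation alone. Of 6 activation and inhibitory receptors, 5 rose adjusted over the list alone and 0 over all genes (adjusted p = 5.28e-05, but adjusted p = 0.0734 with an estimated correlation), with LAG3 at 0.55 and HLA-DRA at 0.68. These 6 of 18 listed genes were HLA-DRA, HLA-DRB1, HLA-DPA1, CD74, ICOS and LAG3, so most were HLA class II genes or CD74. CD69, CD38, CTLA4 and TIGIT were below the detection filter, and PDCD1 had no probe of its own symbol. Of 16 type I interferon response genes, 1 rose over all genes and 4 adjusted over the list alone (adjusted p = 0.000291, but adjusted p = 0.132 with an estimated correlation), and IFI6 had a change of 0.63. Of 16 STAT5-responsive genes, 1 rose over all genes and 3 adjusted over the list alone (adjusted p = 0.00443, but adjusted p = 0.245 with an estimated correlation). These 3 included SOCS1 at 0.98 (adjusted p = 0.0587) and OSM at 0.93. SOCS1 and SOCS3 encode inhibitors of signalling and OSM a cytokine. The BCL2 family list (adjusted p = 0.0227, but adjusted p = 0.132 with an estimated correlation) had 0 of 10 genes past either way of adjusting. The glucocorticoid response list (adjusted p = 0.0227, but adjusted p = 0.3 with an estimated correlation) had 2 of 7 adjusted over the list alone, with SGK1 at 0.90. The oxidative phosphorylation list (adjusted p = 0.0227, but adjusted p = 0.533 with an estimated correlation) had 0 of 36 genes past. The immediate early and dissociation stress list (adjusted p = 0.0424, but adjusted p = 0.54 with an estimated correlation) had 2 of 17 genes higher and 1 lower adjusted over the list alone. Monocyte and dendritic cell markers were also called higher (adjusted p = 0.00216, but adjusted p = 0.3 with an estimated correlation), with 0 of 9 genes past and S100A9 at 1.22. They moved beside the HLA class II genes of the activation list. With 1 animal left out, the call of monocyte markers ended without anti-IL-15 animal 6 (mean 0.19), and that of the BCL2 family without anti-IL-15 animal 1 (0.17) or 4 (0.14). The glucocorticoid call ended without anti-IL-15 animal 1 (0.17), 3 (0.21) or 4 (0.22). The oxidative phosphorylation call ended without anti-IL-15 animal 2 (0.076), 4 (0.018) or 5 (0.081), and the mean was 0.17 without animal 1. The immediate early call ended without IgG1 animal 3 or 5 (0.21) and without anti-IL-15 animal 1 (0.17), 4 (0.20), 5 (0.19) or 6 (0.039), and the mean was 0.33 without animal 2.

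The list of IL-15 and common gamma chain receptors and kinases and that of proliferation were not called in CD8 TCM after anti-IL-15. The 10 detected genes of IL-15 and common gamma chain receptors and kinases had a mean change of 0.0051 and a median of -0.0028, opposite in sign, and 0 passed in limma (adjusted p = 0.893). IL15 had the lowest p, with a change of 0.28 (adjusted p = 0.609). STAT5B had a change of -0.19, IL7R of -0.16, STAT5A of 0.14 and IL2RA of 0.14. The 27 proliferation genes had a mean change of 0.036 (adjusted p = 0.526), with MKI67 below detection, and the 11 memory quiescence and lymph node homing genes one of -0.088 (adjusted p = 0.439). Glycolysis (adjusted p = 0.123; 1 of 16 genes over all genes, SLC2A3, and 2 adjusted over the list alone), CD8 T cell identity (0.183), unfolded protein and amino acid stress (0.263), CD4 T cell identity (0.439) and platelet markers (0.635) were not called either, each value being a camera adjusted p. Nor were regulatory T cell markers (0.697), erythroid markers (0.712), B cell markers (0.714), chemokine receptors and integrins (0.841), cholesterol biosynthesis (0.841), gamma-delta and innate-like markers (1 gene, 0.918) and cytosolic ribosomal proteins (0.988).

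After the IgG1 control antibody, 0 of 8626 genes passed in CD8 TCM in limma, and 604 had an unadjusted p under 0.05. The lowest p values were for AAK1 (0.72), TACR2 (0.69), PACSIN2 (-0.47), CCDC47 (-0.51) and TBC1D19 (-0.65), each with adjusted p = 0.688. Camera called 5 lists higher: cytosolic ribosomal proteins (adjusted p = 3.17e-05, but adjusted p = 0.37 with an estimated correlation), cytotoxic effectors (0.00191, but adjusted p = 0.336 with an estimated correlation) and oxidative phosphorylation (0.00208, but adjusted p = 0.58 with an estimated correlation). The others were erythroid markers (0.00756, but adjusted p = 0.336 with an estimated correlation) and effector regulators (0.0416, but adjusted p = 0.336 with an estimated correlation). None of the 5 had a gene past either way of adjusting in limma. The mean change of the 11 cytotoxic genes was 0.27 after IgG1 against 0.68 after anti-IL-15, but without IgG1 animal 5 the first was 0.11 and its call ended. The effector regulator call ended without IgG1 animal 1 (0.12), 3 (0.12), 4 (0.13) or 5 (0.083). Without IgG1 animal 3 the calls of oxidative phosphorylation (0.067) and erythroid markers (0.45) ended.

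The difference between the antibodies tests the effect of anti-IL-15 over time and handling. In CD8 TCM, 0 of 8626 genes passed for this difference in limma, and 654 had an unadjusted p under 0.05. None of the 15 genes above is therefore shown to differ from the control animals gene by gene. The lowest p values were for ISM1 (difference 1.07 ± 0.20, adjusted p = 0.58), TRAK1 (1.32), IFI27 (1.44), SLC2A3 (1.06) and TBC1D19 (0.91), the last 4 with adjusted p = 0.607. On data simulated at the spread of this comparison over 8623 genes, a difference of 0.5 was recovered for 5.97% of 67 genes, one of 1 for 73.1% of 67 genes and one of 2 for 100% of 66 genes. Camera called 6 lists higher for the difference: activation receptors (adjusted p = 0.00207, mean 0.64), monocyte and dendritic cell markers (0.00319, mean 0.72), type I interferon response (0.0032, mean 0.32), cytotoxic effectors (0.0145, mean 0.42), BCL2 family (0.0275, mean 0.27) and NK cell markers (0.0275, mean 0.34). Adjusted over the list alone, 3 of 6 activation receptors, 2 of 9 monocyte markers, 2 of 16 interferon genes, 1 of 11 cytotoxic effectors, 0 of 10 BCL2 family genes and 2 of 8 NK markers passed, and over all genes 0 did in limma. Most of these 6 activation genes are HLA class II genes or CD74. Ribosomal protein genes were called lower (0.0032, mean -0.16), with 0 of 46 past either way of adjusting. All 7 calls ended with an estimated correlation, at adjusted p = 0.321 for activation receptors, the BCL2 family and NK markers, adjusted p = 0.337 for interferon, adjusted p = 0.37 for monocyte markers and cytotoxic effectors, and adjusted p = 0.445 for ribosomal proteins. With 1 animal left out, the ribosomal call ended without anti-IL-15 animal 1 (mean -0.099), and monocyte markers had a mean of 0.45 without anti-IL-15 animal 6. Without anti-IL-15 animal 4, whose post-treatment array stood apart, the calls of interferon (0.27), cytotoxic effectors (0.36), the BCL2 family (0.23) and NK markers (0.30) ended. The cytotoxic call also ended without IgG1 animal 2 (0.36) or 6 (0.33) or anti-IL-15 animal 5 (0.36), and that of the BCL2 family without IgG1 animal 5 or 6 (0.25). That of NK markers also ended without IgG1 animal 6 (0.30) or anti-IL-15 animal 2 (0.34) or 5 (0.31).

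In CD4 TCM after anti-IL-15, 3 genes of interferon and cytokine feedback were higher than before. IFI27 rose by 1.797 ± 0.296 (moderated SE, 12 animals in the fit; 3.47-fold, adjusted p = 0.0249), SOCS1 by 1.05 ± 0.14 (2.07-fold, adjusted p = 0.00525) and IRF1, a transcription factor of the interferon response, by 1.03 ± 0.17 (2.04-fold, adjusted p = 0.0249), each in 6 of 6 animals. These were the 3 of 8923 genes past the threshold in limma, and 507 had an unadjusted p under 0.05. BHLHE40 (1.09, adjusted p = 0.0755) and NFIL3 (0.64, adjusted p = 0.181), transcription factors of effector differentiation, had the next lowest p values and did not pass. The count was 0 without anti-IL-15 animal 4, 6 without anti-IL-15 animal 5 and 17 without anti-IL-15 animal 6. IFI27 had its largest change, 3.70, in anti-IL-15 animal 3, whose arrays stood apart, and was at 1.42 and past the threshold without it. IRF1 did not pass without anti-IL-15 animal 1 (adjusted p = 0.106) or 2 (adjusted p = 0.158). The count was 0 without the replicate block, and it was also 0 with the sorted cell count as a covariate. Sorted CD4 TCM were at 0.527 of the pre-treatment number after anti-IL-15 and at 0.802 after IgG1 (geometric means). Fewer sorted cells therefore stay open as a source of these 3 calls. Gene lists were not tested with this covariate.

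Lists in CD4 TCM after anti-IL-15 centred on interferon and effector genes. Of 16 type I interferon response genes, 1 rose over all genes and 2 adjusted over the list alone (camera adjusted p = 1.06e-05, and adjusted p = 0.0131 with an estimated correlation), with MX1 at 0.80. Of 13 effector regulators, 0 passed over all genes in limma and 6 rose adjusted over the list alone (adjusted p = 2.56e-05, and adjusted p = 0.0131 with an estimated correlation), with PRDM1 at 1.01 and ID2 at 0.73. Of 9 cytotoxic effector genes, 0 passed over all genes and 2 rose adjusted over the list alone (adjusted p = 0.000227, and adjusted p = 0.0131 with an estimated correlation), with GZMK at 0.84 and GNLY at 0.70. The glucocorticoid list (4 of 7 adjusted over the list alone; adjusted p = 0.000227, but adjusted p = 0.256 with an estimated correlation) and the immediate early list (3 of 17 adjusted over the list alone; adjusted p = 0.000456, but adjusted p = 0.167 with an estimated correlation) were called higher with the preset correlation alone. So were STAT5-responsive genes (1 of 16 over all genes and 3 adjusted over the list alone; adjusted p = 0.00108, but adjusted p = 0.106 with an estimated correlation) and activation receptors (0 of 10 either way; adjusted p = 0.0222, but adjusted p = 0.106 with an estimated correlation). With 1 anti-IL-15 animal left out, the activation call ended without animal 3 (mean 0.091) or 5 (0.145), the glucocorticoid call without animal 3 (0.24) and the immediate early call without animal 6 (0.15). Proliferation genes had a mean change of -0.12 (adjusted p = 0.0631), and the 9 detected IL-15 and common gamma chain genes one of 0.019 with a median of -0.028, opposite in sign (adjusted p = 0.531), and 0 past in limma. JAK1 had a change of -0.18 and STAT5A of 0.27.

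**Figure D2:**
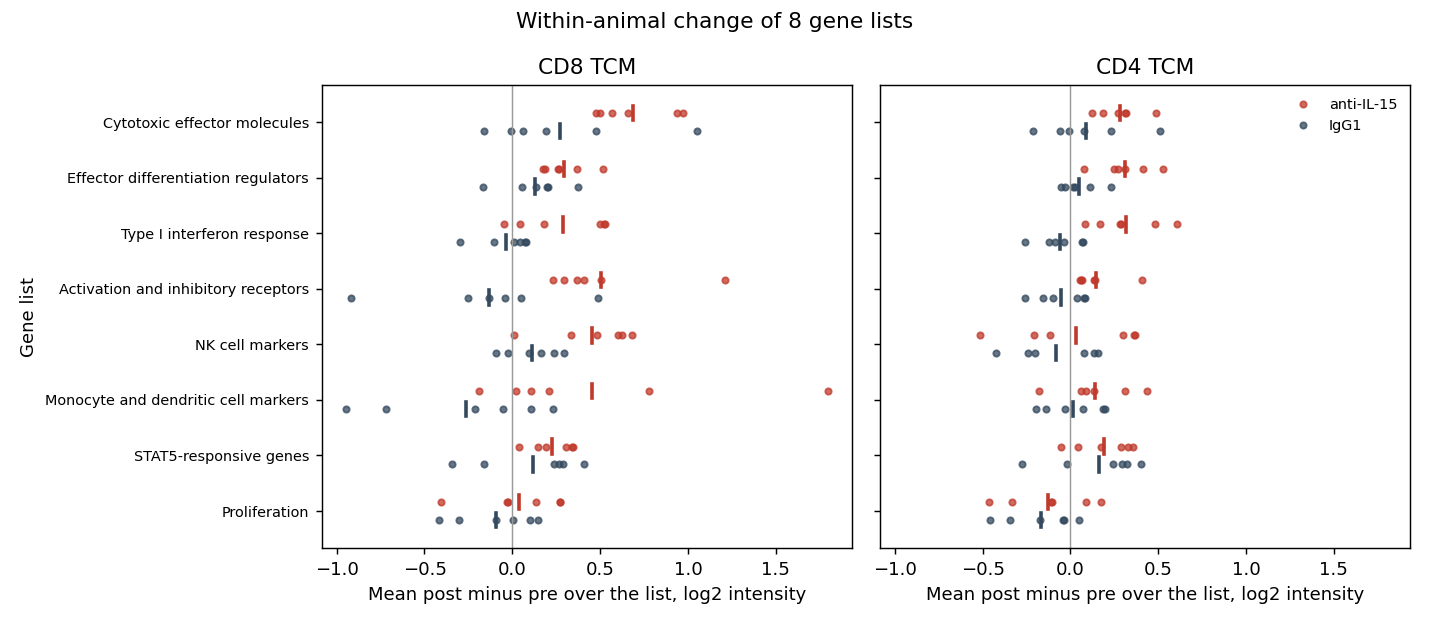
Mean post-treatment minus pre-treatment log2 intensity over the genes of 8 lists, in CD8 and CD4 TCM. Each point is 1 of 6 animals per antibody and each bar is their mean; the cytotoxic list in CD8 TCM averaged 0.68 after anti-IL-15 and 0.27 after IgG1.

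In CD4 TCM after IgG1, 0 of 8923 genes passed in limma and 313 had an unadjusted p under 0.05, and the lowest p was that of SOCS1 (0.76 ± 0.14, adjusted p = 0.325, higher in 6 of 6 animals). DUSP8 (0.61), ACIN1 (0.49), RNA28SN5 (-1.14) and PREX1 (0.56) followed with adjusted p = 1. Proliferation genes were called lower (adjusted p = 3.98e-05, but adjusted p = 0.465 with an estimated correlation; mean -0.17, 0 of 31 past) and STAT5-responsive genes higher (adjusted p = 0.0134, but adjusted p = 0.465 with an estimated correlation; 2 of 16 adjusted over the list alone). Without IgG1 animal 2 the proliferation mean was -0.11. The STAT5 call ended without IgG1 animal 1 (0.13), 2 (0.11), 3 (0.13) or 4 (0.145), and the mean was 0.25 without animal 6. For the difference between antibodies, 0 of 8923 genes passed in limma and 338 had an unadjusted p under 0.05. IFI27 had a difference of 2.01 ± 0.42 (adjusted p = 0.903), MAP2K2 of -1.06 (adjusted p = 0.903). EHMT2 (-0.81), OSBPL3 (-0.72) and OAZ2 (-0.87) had adjusted p = 0.998. For SOCS1 the difference was 0.29. The interferon list was higher after anti-IL-15 than after IgG1 with both kinds of test (mean difference 0.38, adjusted p = 9.69e-06, and adjusted p = 0.0288 with an estimated correlation), with 1 of 16 genes past adjusted over the list alone and 0 over all genes. Its largest change was in anti-IL-15 animal 3 (0.61), whose CD4 arrays stood apart; without that animal the mean difference was 0.321 and the call at the preset correlation was made again. Effector regulators (2 of 13 adjusted over the list alone; adjusted p = 0.00388, but adjusted p = 0.0515 with an estimated correlation), activation receptors (0.0417, but adjusted p = 0.127 with an estimated correlation), cytotoxic effectors (0.0467, but adjusted p = 0.141 with an estimated correlation) and the unfolded protein list (0.0467, but adjusted p = 0.298 with an estimated correlation) were called higher with the preset correlation alone. Leaving out 1 animal ended the last 3 calls: the activation call without IgG1 animal 2, 4 or 6 or anti-IL-15 animal 3, 5 or 6 (means from 0.145 to 0.199), and the cytotoxic call without IgG1 animal 2, 3, 4 or 6 or anti-IL-15 animal 4, 5 or 6 (0.134 to 0.192). The unfolded protein call ended without IgG1 animal 2, 3, 4 or 5 or anti-IL-15 animal 3 or 6 (0.121 to 0.199). On simulated data of 8919 genes, a difference of 0.5 was recovered for 7.46% of 67 genes, one of 1 for 77.6% of 67 and one of 2 for 100% of 66.

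The changes in the 2 cell types ran in parallel in part. Of the 15 genes past the threshold in CD8 TCM, 14 were tested in CD4 TCM, all 14 had the same sign there and 1 (IFI27) passed. In CD4 TCM of the IgG1 animals the mean change had that sign too, except for AGER, GNLY, IFI27 and PDE9A. The shared sign alone is therefore not particular to anti-IL-15. Across 8175 genes the change after anti-IL-15 in CD8 correlated with that in CD4 at r = 0.38, against r = 0.15 after IgG1. Genes are not independent replicates. The test of whether the antibody effect differed between CD8 and CD4 TCM gave 0 of 9355 genes in limma, with 269 at an unadjusted p under 0.05. That fit took the CD8 and CD4 changes of an animal as independent, although both came from the same blood. A change shared by both cell types of an animal therefore stayed in its error, and differences could be missed. TBC1D19 (1.42, adjusted p = 0.185), ISM1 (1.41, adjusted p = 0.24), IL17D (-1.15), OAZ2 (1.43) and MRRF (-1.09) had the lowest p values. Ribosomal protein genes had a lower effect in CD8 (mean -0.17, adjusted p = 0.00709, but adjusted p = 0.714 with an estimated correlation) and monocyte and dendritic cell markers a higher one (mean 0.65, adjusted p = 0.0113, but adjusted p = 0.714 with an estimated correlation), with 0 genes of either list past. The ribosomal call ended without IgG1 animal 3 or 4 or anti-IL-15 animal 1, 3 or 6 (means from -0.143 to -0.106). The monocyte call ended without IgG1 animal 5 (0.565) or 6 (0.488) or anti-IL-15 animal 3 (0.561) or 6 (0.422). On simulated data of 9350 genes, an effect difference of 0.5 was recovered for 4.48% of 67 genes, one of 1 for 32.8% of 67 and one of 2 for 95.5% of 66. The simulated noise was independent between the cell types of an animal too, so these shares do not show the cost of the ignored pairing.

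Before treatment the animals of both antibody groups were compared as a check. In CD8 TCM 0 of 8626 genes differed in limma, with 551 at an unadjusted p under 0.05, and PTPN2 (-0.90, adjusted p = 0.164), KCNA3 (-0.66), RBM26 (-0.85), FAM110A (0.60) and NFU1 (-0.60) had the lowest p values. In CD4 TCM 0 of 8923 genes passed in limma, with 1027 at an unadjusted p under 0.05, and CHD2 (-0.88, adjusted p = 0.0961), DLST (0.83, adjusted p = 0.0961), GANAB (1.52), GIGYF1 (0.70) and ISOC1 (-1.15) had the lowest p values. The 1027 exceeded the numbers in CD4 TCM after anti-IL-15 (507), after IgG1 (313) and for their difference (338). The 0 genes therefore do not show that the CD4 groups were alike before treatment. The CD4 count was 4 without IgG1 animal 2.

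CD8 and CD4 TCM of the 12 animals before treatment differed in 3374 of 9355 genes in limma, 1430 higher and 1944 lower in CD8, and 4198 had an unadjusted p under 0.05. CD8A, the coreceptor chain that defines CD8 T cells, was higher by 7.16 ± 0.16 (143-fold). The protease CTSW, undetected in CD4 TCM, was at least 10.3-fold higher, and the granzymes GZMM, GZMK and GZMH were higher by 3.45, 3.24 and 2.61. GNLY was higher by 2.96, TENT5A by 2.64, EOMES, a transcription factor of CD8 memory, by 2.51, and BEND5 by 2.41. KLRD1 was at least 3.51-fold higher. Lower in CD8 were RAB11FIP5 (-2.06), the transcription regulators TOX2 (-2.04) and MAF (-1.91), CTSL (-1.82), CHST15 (-1.77), the gut-homing chemokine receptor CCR9 (-1.75), DPYSL2 (-1.72), ARID5B (-1.61) and CTNNA1 (-1.59). PTPN13, undetected in CD8 TCM, was at least 2.72-fold lower. Each of these 20 genes went the same way in 12 of 12 animals. Of 11 cytotoxic effectors, 9 were higher (adjusted p = 2.42e-14, and adjusted p = 0.000424 with an estimated correlation), as were 5 of 5 CD8 identity genes (adjusted p = 8.73e-09, and adjusted p = 0.00102 with an estimated correlation), with equal counts adjusted over the list alone. The CD4 T cell identity list was not called by camera, and the gene CD4 was below the detection filter in both cell types. Ribosomal protein genes (17 higher and 1 lower of 46; adjusted p = 0.000485, but adjusted p = 0.355 with an estimated correlation) and NK cell markers (3 of 8, and 5 adjusted over the list alone; adjusted p = 0.00399, but adjusted p = 0.167 with an estimated correlation) were called higher with the preset correlation alone. So were B cell markers (2 of 4; adjusted p = 0.0408, but adjusted p = 0.309 with an estimated correlation) and monocyte and dendritic cell markers (5 of 9, and 6 adjusted over the list alone; adjusted p = 0.0408, but adjusted p = 0.557 with an estimated correlation). The B cell call ended without IgG1 animal 3 (0.687) or 4 (0.655) or anti-IL-15 animal 5 (0.66), and the monocyte call without IgG1 animal 5 (0.473) or anti-IL-15 animal 5 (0.465) or 6 (0.515). Among the IL-15 and common gamma chain genes, IL4R, the receptor of interleukin 4, was higher in CD8 (0.77, adjusted p = 2.88e-06), as was IL2RB (0.30, adjusted p = 0.0159), a receptor chain for IL-15, and IL7R was lower (-0.39, adjusted p = 0.026). CD8 samples came from far fewer sorted cells, so cell type and input are confounded. With the cell count as a covariate 44 genes passed, and in animals 1 to 4 alone, chosen after seeing the data, 1870 passed.

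The number of sorted CD4 TCM was lower after anti-IL-15 in 6 of 6 animals, at 0.527 of the pre-treatment number (geometric mean; exact sign-flip p = 0.03125, two-sided, the smallest that 6 animals allow, and 0.1875 adjusted over 6 tests). After IgG1 it was 0.802 of that number (4 of 6 lower, exact p = 0.281), and the ratio between antibodies was 0.657 (exact permutation p = 0.0887). Sorted CD8 TCM were at 0.787 after anti-IL-15 (5 of 6 lower, exact p = 0.125) and at 0.790 after IgG1 (4 of 6 lower, exact p = 0.25), with a ratio between antibodies of 0.997 (exact permutation p = 0.987). Mean counts fell from 617667 ± 221300 (SD, n = 6) to 327333 ± 121170 for CD4 TCM with anti-IL-15. A sorted number depends on the blood volume as well as on the cells' frequency, and the labels give no volume.

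**Figure D3:**
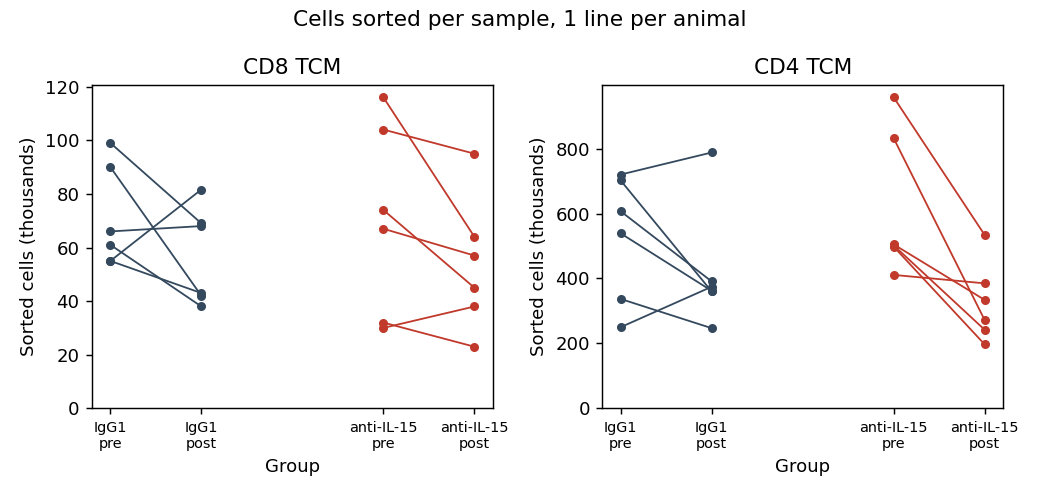
Sorted cells per sample on the vertical axis, before and after treatment for CD8 and CD4 TCM. Each line is 1 animal, 6 per antibody; sorted CD4 TCM were lower after anti-IL-15 in 6 of 6 animals and after IgG1 in 4 of 6.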

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

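The tests of handling, cell number, NK cells, effector memory cells and sample splits in this part were chosen after the result was seen. For a sample far from the others, 73 groups of 6 were tested and chance alone would mark 3.65 of them; 5 were marked.

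For the 15 genes past the threshold in CD8 TCM after anti-IL-15, with the sorted cell count as a covariate the median change was 1.08 (median SE 0.209) against 0.995 (0.189) without it, and 7 of them passed with the wider errors, which argues against fewer cells as the whole source. Of 32 exchanges of pre and post within animals, 1, the real one, gave as many genes. The real value was 15 and the highest other 0. This argues against chance without excluding it. A share of 1 in 32 is the smallest that 6 animals allow, and the test was chosen after the count was seen. Choosing genes by their change raises that change, so 15 genes of lowest p were chosen without 1 anti-IL-15 animal at a time: the animals left out averaged 0.60 ± 0.07 (SE, n = 6), against 1.07 for the 15 genes in the animals that chose them. The IgG1 animals averaged 0.180 ± 0.071 in the same direction (SE, n = 6; above 0 in 6 of 6, exact sign-flip p = 0.03125), and their mean plus 2 SE, 0.322, was not below 1/2 of the 0.60 of the animals left out, so time and handling cannot be told apart from the antibody as the main source. An effect of blocking IL-15 stays open too, since the test against IgG1 gave 0 genes in limma (654 at an unadjusted p under 0.05).

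Cytotoxic and NK-associated genes were higher in CD8 TCM after anti-IL-15, with a mean change of 0.68 for the cytotoxic list. NK cells among the sorted cells are a candidate source that stays open: 4 NK markers outside that list averaged 0.45 ± 0.39 (SD, n = 6), which exceeds 1/2 of the cytotoxic change by 0.103 (exact sign-flip p = 0.531). The markers moved apart, with KLRD1, which T cells also express, at 1.09, TYROBP at 0.62, NCR3 at 0.06 and the abundant FCGR3A at 0.01, whose high level before treatment would hide a small share; the sort for TCM would be meant to remove NK cells. Effector memory T cells cannot be told apart from a change within TCM: the memory list averaged -0.088 (exact sign-flip p = 0.25, lower in 4 of 6 animals), and its high level in central memory cells would hide a small share. After IgG1 the list averaged -0.093 in CD8 TCM, so this value was not particular to anti-IL-15.

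HLA-DRA, HLA-DRB1, HLA-DPA1 and CD74 were averaged, and HLA class II in this paragraph means this set, CD74 included. It changed by 0.53 ± 0.65 (SD, n = 6) in CD8 TCM after anti-IL-15 and by -0.16 ± 0.55 after IgG1 (exact permutation p = 0.0455). Monocytes or dendritic cells among the sorted cells, which the sort for TCM would be meant to remove, are a candidate source: over 12 animals the change of HLA class II rose with that of their markers at r = 0.89 (permutation p = 0.00064, adjusted p = 0.00225 over 5 relations; rho = 0.69, permutation p = 0.0157). The relation was r = 0.48 without the 2 animals farthest out and r = 0.39 in the 8 animals numbered 1 to 4, so it rests largely on few animals. Animals 5 and 6 are too few (4) for a value. Within anti-IL-15 the relation was r = 0.90 and within IgG1 r = 0.76. The permutation shuffled all 12 animals, so its p also reflects the difference between antibodies. Against B cell markers r was -0.34 (permutation p = 0.284, rho = -0.29, permutation p = 0.367). The upper limit was 0.295, just under the bound of 0.3 set beforehand, which argues only narrowly against B cells as the whole source. Within anti-IL-15, where HLA class II was higher, r was -0.61, and B cell markers averaged -0.068 with 2 of 6 animals above 0. Within IgG1 r was 0.89 and these markers averaged 0.19, so a share of B cells stays open.

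In CD8 TCM after IgG1, animal 6 lay apart from the others for IFI27, with a change of -0.71 against 0.30 to 0.58. In the same group animal 2 lay apart for IFFO1, with -0.0802 against 0.21 to 0.32. The activation receptor list lay apart in anti-IL-15 animal 6 of CD8 TCM, at 1.21 against 0.23 to 0.51, and in anti-IL-15 animal 3 of CD4 TCM, at 0.41 against 0.06 to 0.14. In CD8 TCM the genes tested in this list were mostly HLA class II genes or CD74. The CD4 sample of anti-IL-15 animal 2 after treatment had 29.4% of probes detected against 27.2% to 28.0% in its group. The antibody effect differed between CD8 and CD4 TCM for 2 lists by camera, with means of -0.17 for ribosomal proteins and 0.65 for monocyte and dendritic cell markers, and both calls ended with an estimated correlation (adjusted p = 0.714). Among 4594 probes with no listed gene, 3 passed the threshold in CD4 TCM after anti-IL-15, all higher, and 0 did after IgG1 in limma (147 at an unadjusted p under 0.05).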

How the results depend on the processing

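Animals 1 to 4 alone, animals 5 and 6 alone and the removal of animals whose arrays stood apart were chosen after seeing the data. The count of 15 genes in CD8 TCM after anti-IL-15 became 28 with the deposited value table, 26 with normexp at offset 50, 28 with no background correction, 29 with a variance trend and robust moderation, 29 at an adjusted p below 0.10 and 35 with both cell types in 1 fit. It became 7 with every probe of a gene, 5 with array weights, 4 without the animals whose arrays stood apart, 1 with the replicate block as a random effect, 1 in animals 1 to 4, and 0 in animals 5 and 6, with no filter on dim probes or with no replicate block; leaving out 1 animal gave 1 to 14. The count of 3 in CD4 TCM after anti-IL-15 became 18 in animals 1 to 4, 6 with both cell types in 1 fit, 5 with array weights, 1 with no filter on dim probes, and 0 with the cell count as a covariate, with no replicate block, with the block as a random effect or in animals 5 and 6; leaving out 1 animal gave 0 to 17. CD4 TCM before treatment went from 0 genes to 2 with the deposited value table, no background correction, an adjusted p below 0.10 or animals 5 and 6, and to 0 to 4 with 1 animal left out. The antibody effect between cell types went from 0 to 1 with array weights or without the animals that stood apart and stayed at 0 in each of the 12 fits with 1 animal left out. CD8 TCM after IgG1 went from 0 to 1 in animals 5 and 6. CD8 against CD4 became 44 with the cell count as a covariate and 1870 in animals 1 to 4, and CTNNA1 (0.088, adjusted p = 0.953) and RPL35 (-1.04, adjusted p = 0.359) reversed with that covariate, which is confounded with cell type. Of 45 list calls, 28 were made with no replicate block and 9 with an estimated correlation. Fewer animals were fitted in the settings that leave animals out; otherwise the cause was not tested. Of 306 values of genes past the threshold after treatment, 138 kept their direction and side, 168 lost the call and 0 reversed. With 1 animal left out, 122 of 204 such values lost the call. TENT5C, outside the naming rule, is not counted in these values.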

Other observations

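The relations between cell types in this part were set out before their values were seen, and the sample splits after. Pooled over both antibodies, animals with a larger interferon change in CD4 TCM had a larger one in CD8 TCM. Over 12 animals the mean change of the interferon list in CD8 TCM followed that in CD4 TCM at r = 0.84 (permutation p = 9e-04, adjusted p = 0.00225 over 5 relations; rho = 0.70, permutation p = 0.0135), at r = 0.66 without the 2 animals farthest out and at r = 0.89 in the 8 animals numbered 1 to 4. It was 0.82 within anti-IL-15 and 0.39 within IgG1. The list mean rose after anti-IL-15 (0.29 in CD8, 0.32 in CD4) and not after IgG1 (-0.034 and -0.060). The permutation shuffled animals across antibodies, so r and its p include this difference and do not test covariation within a group. The cytotoxic list gave r = 0.78 (permutation p = 0.00302, adjusted p = 0.00503; rho = 0.87, permutation p = 0.00037), r = 0.66 without the 2 farthest, r = 0.63 in animals 1 to 4, 0.46 within anti-IL-15 and 0.77 within IgG1. The effector regulator list gave r = 0.56 (permutation p = 0.0546, adjusted p = 0.0683; rho = 0.59, permutation p = 0.0479), which leaves open whether its change is shared. Animals 5 and 6 of both groups make 4 animals, too few for a value of their own. A change of the whole animal stays a hypothesis for the interferon and cytotoxic lists, because the permutation did not keep the antibody groups apart. No p within a group was computed. Cells of both types sorted from 1 blood sample also share its handling.

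Other splits of the samples were counted for the remaining comparisons. For CD4 TCM after anti-IL-15 chance cannot be excluded: 4 of 32 exchanges gave at least the real 3 genes, and the highest other gave 237. That split exchanges pre and post in animals 1, 2 and 3 and keeps animals 4, 5 and 6, so many genes moved in opposite directions in these sets of animals, a structure of the samples whose source, the response to the antibody included, was not tested. All splits keep the pairs. For CD8 against CD4, 1 of 100 splits, the real one, gave as many genes, which argues against chance. The real value was 3374 and the highest other 1455. Where the real value was 0 there was no count to test, and every split gives at least as many by construction: 32 of 32 for CD8 TCM after IgG1 (highest other 1) and for CD4 TCM after IgG1 (highest other 0), and 100 of 100 for the antibody difference in CD8 (1), that in CD4 (0), the groups before treatment in CD8 (1) and in CD4 (51), and the antibody effect between cell types (1).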
